A study of Mus musculus with 6 samples.

How the data were processed

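Total RNA of 6 samples of mouse primary cortical neurons was studied, 3 labelled control and 3 labelled activated. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted, and strand-specific libraries were sequenced as paired reads of 150 bp on a NovaSeq instrument. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.2b, and edgeR was used for their differential expression. Each deposited file held counts per gene as written by STAR, with an unstranded column and a column for each strand. The aligner's parameters and the annotation release were not given in the sources used here.

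Counts in the reverse-strand column were used, since reads on the opposite strand made up only 4.10% of both strands in labelled control and 4.15% in labelled activated libraries. Each file also held 4 lines naming no gene, which were kept out of library sizes and tests. Their shares of all reads averaged 27.7% and 32.6% for reads outside annotated exons in labelled control and labelled activated libraries, 8.75% and 7.99% for unmapped, 5.77% and 5.20% for multimapping, and 0.933% and 0.792% for ambiguous reads. Gene reads ranged from 17753000 to 32920000 per library. Gene names, types, coordinates and transcript lengths came from GENCODE mouse release 21, in which 55144 of 55385 gene identifiers were found once version suffixes were set aside.

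Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 18132 genes. Libraries were scaled by TMM, and the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) compared the groups with no other term. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The log2 CPM values used in the list tests had a prior count of 2. Log2 fold changes came from the edgeR fit at its default prior count and are positive where the libraries labelled activated were higher. Standard errors were derived as the absolute log2 fold change over the square root of F. CPM values are scaled by TMM and given as mean ± SD of 3 libraries. The biological coefficient of variation was 0.076. Gene lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the 21 lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way and not whether they differ from other genes. Differences between whole libraries were tested with exact permutations, of which the smallest possible p is 0.1, and differences between groups of genes with 100000 permutations (seed 1).

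The 21 lists covered rapid and later activity-induced genes, MAP kinase and GTPase feedback regulators, cap formation with cap methylation and cap binding, NF-kB and cytokine genes, heat shock and unfolded protein response, SRF and cytoskeleton genes, ionotropic glutamate and GABA-A receptors, voltage-gated ion channels, synaptic vesicle genes, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear retained long noncoding RNAs with splicing factors, circadian clock genes, excitatory and inhibitory neuron markers, markers of astrocytes, the oligodendrocyte lineage and microglia, markers of endothelial, mural and fibroblast cells, and cell cycle genes. The lists, the tests, the filter and the rule for named genes were fixed before the data were examined. By that rule the text names Rnmt and the members of the cap list past the threshold, the 12 largest increases and 12 largest decreases, and the 4 members of each list with the smallest p. A few genes that this rule selects are not reported here. For the largest changes, a gene symbol, a mean log2 CPM of at least 0 and no overlap between groups were required. Exceptions chosen after their values were seen were Fos, Junb, Nr4a1, Egr1, Zfp36, Maff, Ccn1, Bdnf, Slc17a7, Slc17a6, Camk2a and Il6, and all genes and gene families of the last part of the text.

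Alternatives were DESeq2 1.42.0 size factors, total counts only, the DESeq2 Wald test, the edgeR likelihood-ratio test, no low-count filter, a filter of 1 CPM in 3 libraries, unstranded counts, the replicate number as a block, and each library left out in turn. Scaling to the neuron marker lists and offsets for transcript length and GC content (splines with 4 degrees of freedom; Biostrings 2.70.1) were added after the data were seen. Gene overlaps used GenomicRanges 1.54.1 and plots matplotlib 3.10.9. The procedure was tested on simulated counts for 18132 genes, where it recovered 42 of 67 genes changed 1.5-fold (62.7%), 47 of 67 changed 2-fold (70.1%) and 62 of 66 changed 4-fold (93.9%), with 12 false calls (7.36% of calls). Only these few genes were changed, some up and some down, whereas 6678 were called in the data. These rates may therefore differ from those of the comparison itself, and the simulation did not test the scaling. No library was left out of the main comparison.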

Results

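RNA of mouse primary cortical neurons was measured by strand-specific sequencing of total RNA from which ribosomal RNA had been depleted. The neurons were isolated at embryonic day 18 and kept for 16 days in vitro. All cultures had been exposed from day 2 to 2.5 uM AraC, an inhibitor of DNA synthesis that limits dividing cells, for 24 hours. The 3 libraries labelled control came from untreated cells. The 3 libraries labelled activated came from cells depolarised with KCl for 5 minutes, washed, and harvested after 30 minutes of recovery. The labels give the KCl concentration as 50 mM in one field and as 50 uM in another, and the data cannot settle which is right. Reads assigned to genes on their own strand numbered 27881000, 22995000 and 32920000 in control replicates 1, 2 and 3, and 17753000, 27681000 and 32740000 in activated replicates 1, 2 and 3. Activated replicate 1 was the shallowest library. The labels do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples.

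The comparison asked how the transcriptome of these neurons differed after brief depolarisation. The direction of the best known activity-induced genes went against the labels: Arc, Npas4, Fosb and Egr2 to Egr4 were lower in all 3 libraries labelled activated than in all 3 labelled control. Groups are therefore named by their labels throughout, and each direction below rests on the labels being right. Of 18132 genes tested, 2945 were higher and 3733 lower in the libraries labelled activated (edgeR quasi-likelihood test, adjusted p below 0.05), so that 55.9% of changed genes were lower. By annotated type, 2269 of 14095 protein-coding genes were higher and 3624 lower, whereas 79 of 490 long intergenic noncoding RNA genes were higher and 16 lower. Log2 fold changes reached at least 1 for 297 higher genes and −1 or below for 50 lower genes, and the median over all tested genes was 0.04. The values of the 2 groups did not overlap for 49.0% of tested genes, where chance gives 10%. The split depended on the scaling: with total counts only, 2089 genes were higher and 4576 lower (68.7% lower). With libraries scaled to the neuron marker lists, which moved the median of all genes by 0.31, 8814 were higher and 629 lower (6.66% lower).

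The 12 largest decreases were led by Fosb (ENSMUSG00000003545.3, chromosome 7, 19302696 to 19310051), which encodes a subunit of the AP-1 transcription factor. Fosb stood at 207 ± 7.61 CPM in labelled control and 39.2 ± 10.7 CPM in labelled activated libraries (SD, n = 3 each), a log2 fold change of −2.39 ± 0.13 (SE; edgeR adjusted p = 1.02e-07). The zinc finger transcription factors Egr2, Egr4 and Egr3 had log2 fold changes of −1.95, −1.91 and −1.45. Gadd45g, of a stress-response family, and Arl4d, a small GTPase, fell by 1.91 and 1.89 on the log2 scale. Arc (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570), a regulator of AMPA receptor trafficking, went from 176 ± 11.8 to 48.9 ± 2.92 CPM (SD, n = 3), a log2 fold change of −1.84 ± 0.07 (SE; edgeR adjusted p = 4.61e-09). Npas4 (ENSMUSG00000045903.9, chromosome 19, 4984355 to 4990316), a neuronal transcription factor induced by calcium entry, went from 159 ± 11.1 to 44.3 ± 3.15 CPM, with a log2 fold change of −1.84 ± 0.07 and the same edgeR adjusted p. The other members of this group were Gm13889 (−1.78), the centriole gene Stil (−1.68), C2cd4b (−1.58) and Sertad1 (−1.57), the last 3 with labelled control means of 2.22, 2.69 and 5.84 CPM.

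The 12 largest increases were all of low abundance. Their means lay between 0.444 and 1.54 CPM in labelled control libraries and between 1.41 and 4.96 CPM in labelled activated ones. They were Tm6sf2, a lipid metabolism gene (log2 fold change 1.79), Cnn1, the smooth muscle calponin (1.78), Chil1, a chitinase-like secreted protein (1.68), the chemokine Cxcl1 (1.67), the death receptor Tnfrsf25 (1.55), the water channel Aqp1 (1.48), the urea transporter Slc14a1 (1.45), the laminin chain Lamc3 (1.44), the collagen-binding integrin Itga11 (1.44), the collagen Col24a1 (1.43), the stress cytokine Gdf15 (1.43) and the EGF receptor ligand Ereg (1.41). Cxcl1 had the smallest edgeR adjusted p of the group, 3.42e-05, with 1.54 ± 0.329 against 4.96 ± 0.148 CPM (SD, n = 3). Slc14a1 lost its call without control replicate 3 (log2 fold change 1.09), and Itga11 moved to 0.44 in unstranded counts.

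Rapid activity-induced genes, which neurons switch on within minutes of calcium entry, were lower as a group in the libraries labelled activated. Of the 42 fixed genes, all tested, 33 fell, 3 rose and 6 did not pass (edgeR; 34 lower and 4 higher when adjusted over the list alone). The list's median log2 fold change was −0.74 (camera adjusted p = 4.33e-12; adjusted p = 0.327 with an estimated correlation). Besides the genes above, Fos went from a mean of 203 to 90.3 CPM (n = 3 each), with 79.0, 78.6 and 113 CPM in activated replicates 1, 2 and 3 and a log2 fold change of −1.16 ± 0.11 (SE). Junb (−1.22), Nr4a1 (−1.05) and Egr1 (−0.94) fell too. The 3 members that rose were Zfp36, which promotes decay of AU-rich mRNAs (1.21), the small Maf protein Maff (9.07 to 17.8 CPM) and the matrix protein gene Ccn1 (0.65). Fos and these 3 were singled out after their values had been seen, as were Junb, Nr4a1 and Egr1. In each library labelled activated the neuron marker lists were also lower and mitochondrial reads made up a larger share, with values given below. With libraries scaled to the neuron marker lists, 25 members were lower and 6 higher, around a median of −0.44.

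**Figure D1:**
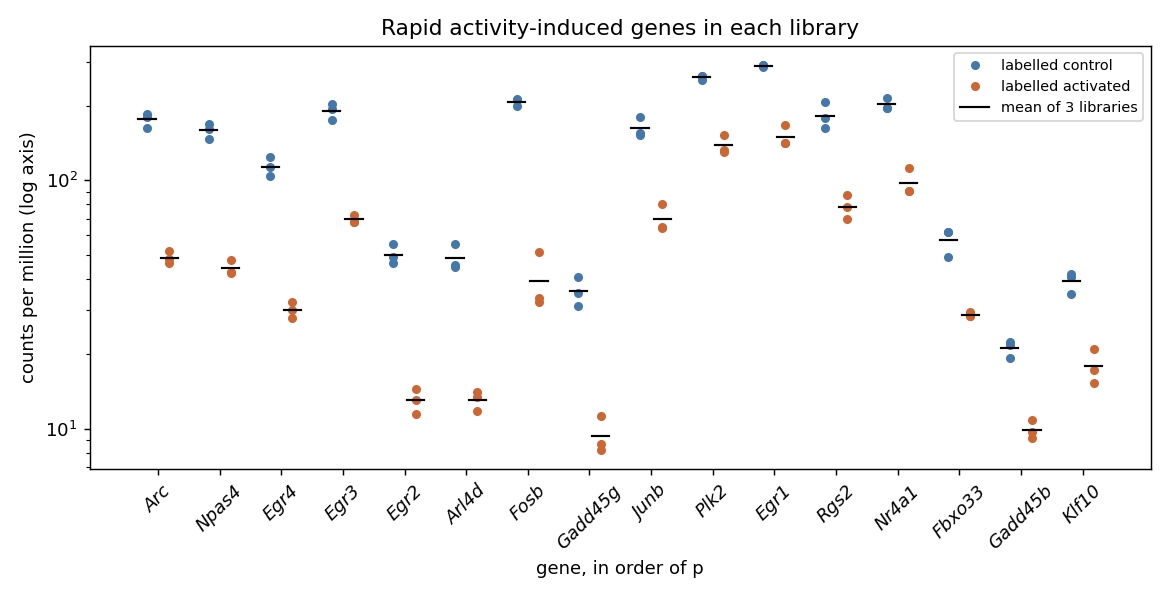
CPM (log axis) of the 16 rapid activity-induced genes with the smallest p, with 1 point per library and bars at the mean of 3 libraries. For each gene all 3 libraries labelled activated lie below all 3 labelled control; Arc, for example, lies between 46.3 and 52.1 CPM against 163 to 186 CPM.

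Later activity-induced genes, whose transcripts accumulate over hours after stimulation, did not change as a group. Of 24 members, 4 fell and 20 did not pass (the same counts adjusted over the list alone), with a median log2 fold change of −0.05 (camera adjusted p = 0.192). Those that fell were the postsynaptic scaffold gene Homer1 (−0.74), Sertad1 (−1.57) and the nuclear receptors Nr4a3 (−0.81) and Nr4a2 (−0.60). Bdnf, the neurotrophin gene, stood at 80.1 ± 4.64 and 80.2 ± 26.9 CPM (SD, n = 3), and its values in activated replicates 1, 2 and 3 were 67.4, 62.1 and 111 CPM. The result rested on activated replicate 3. Without it the list's median was −0.21 (camera adjusted p = 0.00127) and Bdnf's log2 fold change was −0.31 (edgeR adjusted p = 0.00237). The list also passed at a median of −0.07 with no low-count filter (camera adjusted p = 0.0481), and its median turned to 0.01 without control replicate 2 and 0.03 without activated replicate 2. Under the neuron marker scaling the median turned to 0.25 and the list passed as lower than the other genes (camera adjusted p = 0.0161).

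Feedback regulators of MAP kinase and small GTPase signalling fell as a group, with 12 of 22 members lower, 2 higher and 8 not passing (the same counts adjusted over the list alone). The median log2 fold change was −0.34 (camera adjusted p = 0.00125; adjusted p = 0.389 with an estimated correlation). The dual-specificity phosphatases Dusp6 and Dusp14 had log2 fold changes of −1.03 and −1.05, the G-protein regulator Rgs4 −0.73 and the GTPase Rem2 −0.99. Under the neuron marker scaling 6 members were higher and 5 lower, around a median of −0.03.

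The series title concerns RNMT, the enzyme that methylates the guanosine cap of mRNA. Rnmt (ENSMUSG00000009535.13, chromosome 18, 68300355 to 68324852, plus strand) was lower in the libraries labelled activated, at 51.9 ± 4.80 CPM against 71.9 ± 6.65 CPM (SD, n = 3 each). Its log2 fold change was −0.47 ± 0.08 (SE; edgeR adjusted p = 0.00064). Ramac, the activating subunit of RNMT, had a log2 fold change of −0.31. Of the 26 genes fixed for cap formation, cap methylation and cap binding, 12 fell, 1 rose and 13 did not pass (edgeR; 13 lower and 1 higher when adjusted over the list alone). The median log2 fold change was −0.21 (camera adjusted p = 0.00425; adjusted p = 0.266 with an estimated correlation). The lower members included genes of methyl donor metabolism, Mat2b (−0.58) and Ahcy (−0.68), the cap-binding protein genes Eif4e (−0.37) and Eif4e2 (−0.24), the helicase gene Eif4a1 (−0.53) and the scaffold gene Eif4g1 (−0.39) of translation initiation, the nuclear cap-binding complex genes Ncbp1 (−0.21) and Ncbp2 (−0.29), the decapping enzyme gene Dcp2 (−0.40) and the translational repressor gene Cyfip2 (−0.34). Its paralogue Cyfip1 rose (0.35). Under the neuron marker scaling, which raised the median of all genes to 0.35, the list's median turned to 0.10 and Eif4e2, Ncbp1 and Ncbp2 changed sign. The list passed there as lower than the other genes (camera adjusted p = 0.0282), a gap that this scaling hardly alters because it moves all genes alike. Rnmt's log2 fold change shrank to −0.16 with no call (edgeR adjusted p = 0.124). Across the other alternatives run Rnmt lay between −0.38 and −0.55 and passed in each. Ramac lost its call without control replicate 1 (−0.31), control replicate 3 (−0.25) or activated replicate 2 (−0.26), Ncbp1 (−0.17) and Ncbp2 (−0.21) without control replicate 2, and Eif4e2 without activated replicate 1 (−0.21).

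**Figure D2:**
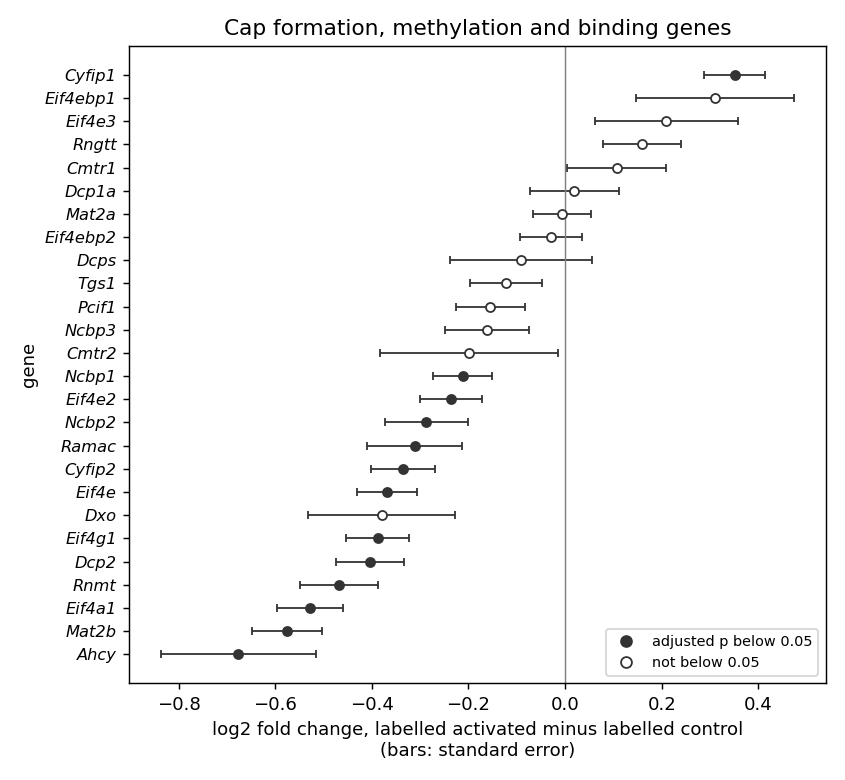
Log2 fold change (labelled activated minus labelled control; bars, standard error) of the 26 genes for cap formation, cap methylation and cap binding, with filled points for an adjusted p below 0.05. Filled points lie between −0.68 for Ahcy and −0.21 for Ncbp1, except Cyfip1 at 0.35; under the neuron marker scaling Eif4e2, Ncbp1 and Ncbp2 changed sign.

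Both lists of neuron markers were lower in the libraries labelled activated, though not every member was. Of 18 inhibitory neuron markers, 10 fell, none rose and 8 did not pass, with a median log2 fold change of −0.42 (camera adjusted p = 0.000195; adjusted p = 0.266 with an estimated correlation) that shrank to −0.11 under the neuron marker scaling. The GABA-synthesising enzyme genes Gad1 and Gad2 fell by 0.81 and 0.70 on the log2 scale, and Pvalb, which encodes parvalbumin, by 1.17. Of 16 excitatory neuron markers, 8 fell, 1 rose and 7 did not pass, with a median of −0.29 (camera adjusted p = 0.0076; adjusted p = 0.266 with an estimated correlation) that turned to 0.01 under the neuron marker scaling, which is built from these lists. The transcription factor genes Bcl11b, Neurod2 and Foxp1 had log2 fold changes of −0.60, −0.59 and −0.44, and Nrgn, a calmodulin-binding postsynaptic protein gene, −0.51. Camk2a, singled out after its values had been seen, was the member that rose (0.36). The vesicular glutamate transporter genes Slc17a7 (0.14) and Slc17a6 (0.15), singled out likewise, were among the excitatory markers that did not pass. Adjusted over each list alone, 10 inhibitory markers were lower and 1 higher, and 8 excitatory markers were lower and 1 higher.

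Synaptic vesicle genes fell in part. Of 23 members, 11 fell, none rose and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.000881; adjusted p = 0.519 with an estimated correlation). The median log2 fold change of −0.11 was −0.07 without activated replicate 2 and −0.18 without activated replicate 3. It turned to 0.19 under the neuron marker scaling, where the list passed as lower than the other genes (camera adjusted p = 0.00287), a gap that this scaling hardly alters. The release machinery genes Cplx1 (−0.80), Vamp1 (−0.69) and Rab3a (−0.57) fell. The vesicular glutamate transporter gene Slc17a7, singled out afterwards, stood at 475 ± 15.8 and 523 ± 54.9 CPM and did not pass (log2 fold change 0.14), but was called without activated replicate 2 (0.21).

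Genes of neuronal membrane excitability did not share the direction of the marker lists. Of 27 ionotropic glutamate and GABA-A receptor genes, 3 rose, none fell and 24 did not pass, with a median of 0.04 (camera adjusted p = 0.449) and none passing when adjusted over the list alone. This median turned to −0.03 with total counts only and to −0.01 without activated replicate 3. The AMPA receptor genes Gria2 (0.22) and Gria3 (0.19) and the kainate receptor gene Grik2 (0.22) rose. Their calls were lost with total counts only (0.15, 0.12 and 0.16 for Gria2, Gria3 and Grik2) and after correction for transcript length and GC content, at 0.07, 0.12 and 0.10 in the same order, and those of Gria3 and Grik2 also without control replicate 2 (0.17 and 0.19) or activated replicate 1 (0.19 and 0.22). Grik2 lost its call without activated replicate 2 as well (0.18). Of 27 voltage-gated channel genes, 5 rose, 2 fell and 20 did not pass, with a median of 0.09 (camera adjusted p = 0.376; 5 higher and 1 lower adjusted over the list alone) that was 0.02 with total counts only and 0.04 without activated replicate 3. The calcium channel genes Cacna1g (0.25) and Cacna1a (0.24) and the sodium channel gene Scn3a (0.20) rose, the last with no call without activated replicate 1 (0.19). Under the neuron marker scaling both lists passed, at medians of 0.34 for receptors and 0.40 for channels. That scaling raised the median of all tested genes to 0.35, so both list medians lay near that of all genes. The potassium channel gene Kcnc2 had a value of −0.24, which lost its call without control replicate 3 (−0.22) or activated replicate 2 (−0.18) and turned to 0.07 under the neuron marker scaling.

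Markers of other brain cell types were higher in the libraries labelled activated. Of 15 astrocyte markers tested (of 16 fixed), 14 rose and none fell, with a median log2 fold change of 0.59 (camera adjusted p = 3.18e-06; adjusted p = 0.327 with an estimated correlation). The glutamate transporter gene Slc1a3 went from 179 ± 5.02 to 289 ± 24.4 CPM (SD, n = 3), the lipoprotein gene Apoe from 238 ± 14.8 to 386 ± 47.6 CPM, and Gja1, which encodes connexin 43, from 27.8 ± 4.77 to 51.8 ± 6.24 CPM. Of 12 endothelial, mural and fibroblast markers tested (of 17 fixed), 7 rose and none fell (median 0.47; camera adjusted p = 0.00106; adjusted p = 0.266 with an estimated correlation), among them the matrix genes Fn1 (0.79) and Col1a2 (0.88), the transporter gene Slco1a4 (0.73) and the pericyte receptor gene Pdgfrb (0.82). Of 8 oligodendrocyte lineage markers tested (of 15 fixed), 4 rose and none fell (median 0.41; camera adjusted p = 0.0206; adjusted p = 0.266 with an estimated correlation), among them the transcription factor genes Olig2 (0.70) and Olig1 (0.54) and the proteoglycan gene Cspg4 (0.81). Of 13 microglia markers tested (of 15 fixed), 8 rose and none fell (median 0.58; camera adjusted p = 0.0367; adjusted p = 0.738 with an estimated correlation). Tyrobp, C1qc and Laptm5 had values of 0.65, 0.77 and 0.72 with overlapping groups. The microglia list lost its call without control replicate 1 (median 0.67), control replicate 3 (0.49), activated replicate 2 (0.64) or activated replicate 3 (0.32), under the neuron marker scaling (0.89) and with fry (adjusted p = 0.293). Without activated replicate 3, Tyrobp, C1qc and Laptm5 had values of 0.41, 0.47 and 0.34 and no call. They also lost their calls without control replicate 3 (0.53, 0.54 and 0.54), C1qc without control replicate 1 (0.85) or activated replicate 2 (0.79), and Laptm5 without control replicate 2 (0.81). Adjusted over the list alone, 14 astrocyte, 8 endothelial, mural and fibroblast, 4 oligodendrocyte lineage and 9 microglia markers were higher and none lower.

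**Figure D3:**
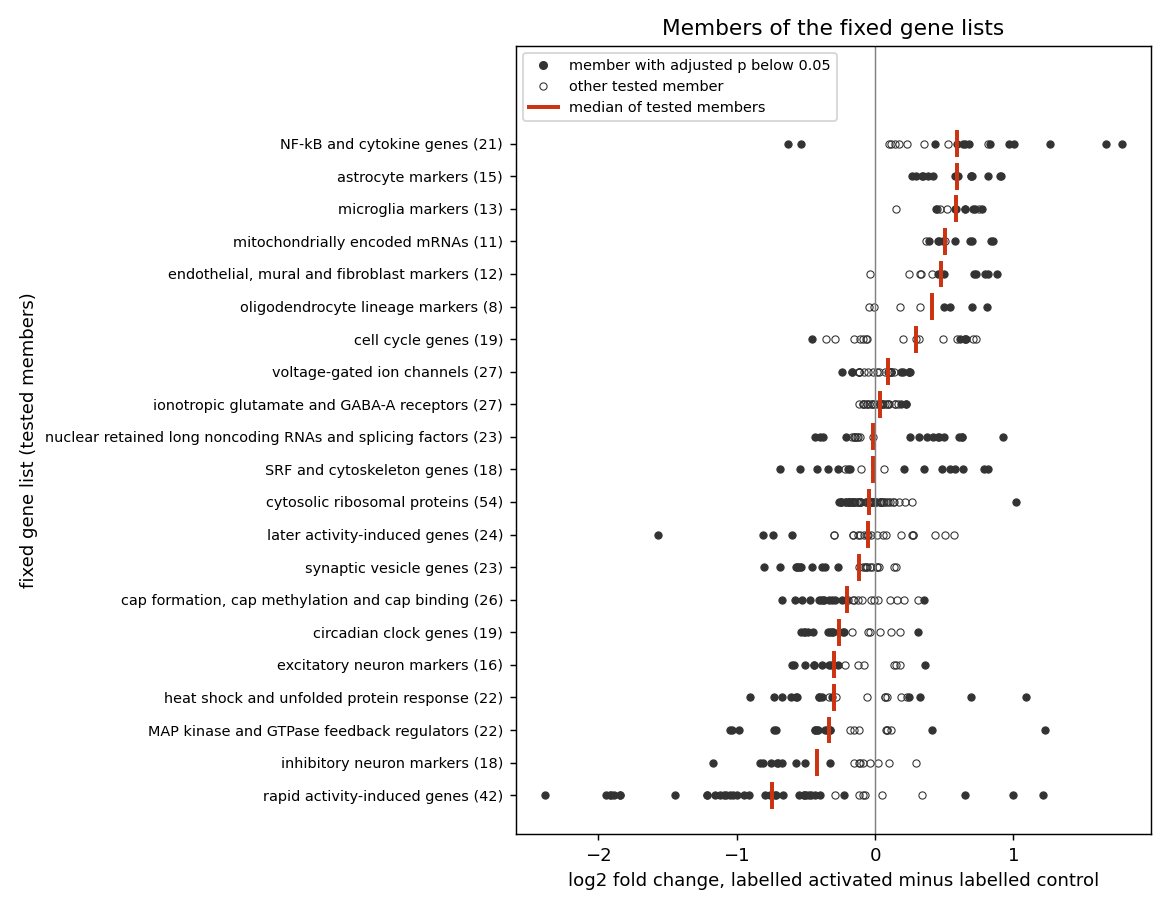
Log2 fold change (labelled activated minus labelled control) of each tested member of the 21 fixed lists, with filled points for an adjusted p below 0.05 and red bars at list medians, under TMM scaling. Medians run from −0.74 for rapid activity-induced genes to 0.59 for astrocyte markers and for NF-kB and cytokine genes. Under the neuron marker scaling the medians of the cap, circadian, excitatory, heat shock, vesicle, later activity-induced, ribosomal, SRF and nuclear RNA lists turn positive. That scaling raised the median of all tested genes to 0.35.

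Cytokine and NF-kB pathway genes rose as a group alongside the glial markers. Of 21 members tested (of 26 fixed), 11 rose, 2 fell and 8 did not pass (15 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 0.59 (camera adjusted p = 0.000502; adjusted p = 0.266 with an estimated correlation). The chemokine gene Cxcl1 (1.67), the adhesion molecule gene Icam1 (0.68) and the cytokine gene Lif rose, and Nfkbib, an inhibitor of NF-kB, fell (−0.63). Il6, singled out afterwards, was near the detection limit at 0.293 ± 0.144 and 1.04 ± 0.231 CPM.

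Heat shock and unfolded protein response genes moved both ways, with 10 of 22 lower, 4 higher and 8 not passing (the same counts adjusted over the list alone). The cytosolic chaperone genes Dnajb1 (−0.91), Dnaja1 (−0.67) and Hsp90aa1 (−0.57) and the stress transcription factor gene Atf4 (−0.73) fell. The list's median of −0.30 passed narrowly (camera adjusted p = 0.0446; adjusted p = 0.738 with an estimated correlation). Its call was lost with total counts only (−0.36), with the filter of 1 CPM (−0.26), with the replicate number as a block (−0.29) and with fry (adjusted p = 0.0589). It was also lost without control replicate 1 (−0.31), control replicate 2 (−0.15), activated replicate 1 (−0.27) or activated replicate 2 (−0.22). Under the neuron marker scaling the list's median turned to 0.01. The list passed there as lower than the other genes (camera adjusted p = 0.00569), a gap that this scaling hardly alters. SRF and cytoskeleton genes were split, with 8 of 18 higher and 7 lower (the same counts adjusted over the list alone; camera adjusted p = 0.888), and their median of −0.02 differed in sign from their mean of 0.08. The median was 0.04 without control replicate 1, −0.05 without control replicate 3, 0.00 without activated replicate 1, 0.02 without activated replicate 2 and −0.08 without activated replicate 3. The actin regulators and actins Cfl1 (−0.69) and Actg1 (−0.54) fell, and the actin crosslinker gene Flna (0.54) and the calponin gene Cnn2 (0.79) rose.

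Mitochondrially encoded transcripts took a larger share of reads in the libraries labelled activated. They made up 25.0%, 23.0% and 21.3% of gene reads in activated replicates 1, 2 and 3, against 17.1%, 14.7% and 16.4% in control replicates 1, 2 and 3 (23.1 ± 1.84% against 16.1 ± 1.24%, SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 11 mitochondrial mRNAs tested (of 13 fixed), 9 rose and none fell (10 higher adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 0.00247; adjusted p = 0.519 with an estimated correlation and 0.0805 with fry). The respiratory chain genes mt-Co1 (0.70), mt-Nd5 (0.69), mt-Nd2 (0.85) and mt-Co3 (0.39) rose. These genes have copies in the nuclear genome, and mt-Co3, at 18.6 CPM against 8105 CPM for mt-Co1 in labelled control libraries, is uncertain because reads that fit several places are not counted. Reads that fell in no annotated exon made up 37.2%, 43.1% and 33.2% of unambiguous reads in activated replicates 1, 2 and 3 and 33.4%, 30.3% and 34.5% in control replicates 1, 2 and 3 (exact permutation p = 0.3).

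Ribosomal protein genes, nuclear RNAs and cell cycle genes gave no list call. Of 54 cytosolic ribosomal protein genes, 8 fell, 1 rose and 45 did not pass, with none passing when adjusted over the list alone (median −0.05; camera adjusted p = 0.183). The list passed with total counts only (−0.11; camera adjusted p = 0.0367), without control replicate 3 (−0.08), with no low-count filter (−0.06) and in unstranded counts (−0.08). Rpl8, Rpl3, Rpl7 and Rps4x had log2 fold changes of −0.25, −0.25, −0.25 and −0.26, all without a call when control replicate 2 was left out (−0.18, −0.16, −0.15 and −0.14) and all positive under the neuron marker scaling. Rps4x also lost its call without activated replicate 1 (−0.27) or activated replicate 2 (−0.21), and many processed pseudogenes share reads with these genes. Of 23 nuclear retained RNAs and splicing factors, 11 rose and 4 fell (the same counts adjusted over the list alone; camera adjusted p = 0.567), with a median of −0.01 and a mean of 0.14. The median turned to 0.09 without control replicate 3 and 0.03 without activated replicate 3, and lay between −0.08 and 0.00 without any other single library. The long noncoding RNAs Mirg (0.93), Neat1 (0.63), Miat (0.63) and Kcnq1ot1 (0.60) rose, in libraries of which activated replicates 1 and 2 also had more reads outside exons. Of 19 cell cycle genes tested (of 20 fixed), 2 rose, 1 fell and 16 did not pass (none higher and 1 lower adjusted over the list alone; median 0.30, camera adjusted p = 0.253). The median was 0.15 without activated replicate 2, 0.18 without activated replicate 3, 0.16 in unstranded counts and 0.61 under the neuron marker scaling. Pcna fell (−0.45), and Rrm2 (0.66) and Mki67 (0.61) rose at means of 1.63 and 2.43 CPM in labelled control libraries; Rrm2 and Mki67 lost their calls without control replicate 2 (0.51 and 0.44), control replicate 3 (0.69 and 0.60) or activated replicate 1 (0.49 and 0.45), and Rrm2 also without activated replicate 2 (0.69).

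Circadian clock genes fell as a group. Of 19 members, 12 fell, 1 rose and 6 did not pass (the same counts adjusted over the list alone), with a median log2 fold change of −0.26 (camera adjusted p = 0.00304; adjusted p = 0.266 with an estimated correlation) that turned to 0.04 under the neuron marker scaling. The repressor genes Nr1d1 (−0.50), Nr1d2 (−0.49) and Cry1 (−0.53) and the clock output transcription factor gene Hlf (−0.45) were among them. Under the neuron marker scaling the list passed as lower than the other genes (camera adjusted p = 0.022), a gap that this scaling hardly alters. Hours of harvest are not given in the labels.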

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

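In this part, the tests on the rapid genes and on cell type markers were chosen after the results they concern had been seen. The tests on TEC loci, whose annotation still awaits experimental evidence, were chosen after the excess of these loci was known but before the tested values were measured. Reads outside annotated exons, which are not part of the gene counts, made up 37.2% of unambiguous reads in activated replicate 1 and 43.1% in activated replicate 2, above the 30.3% to 34.5% of the 3 libraries labelled control. Reads on the strand opposite to the gene were more numerous in the libraries labelled activated for 345 of 7563 genes tested and fewer for 488 (edgeR adjusted p below 0.05). An annotated gene on the other strand, whose own reads these can be, overlapped 275 and 459 of them, against 6057 of 7551 tested genes with coordinates, so for higher genes the overlap was about as common as among all.

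As a group, rapid activity-induced genes were lower in each library labelled activated. A lower neuron share would have moved them as far as the neuron markers, if all neuronal genes moved alike. Their median of −0.74 (42 genes) lay −0.42 from the −0.32 of the 34 neuron markers (permutation p = 0.0012). But the markers did not move alike, with Pvalb at −1.17 and Camk2a at 0.36. The permutations also treat genes as independent, while the estimated correlation among rapid genes was 0.53. The rapid list thus fell further than the markers, but whether a lower neuron share was the whole cause was left open. Exchanged labels were left open: the count of libraries on the side of the rapid list's mean log2 CPM opposite to their label, 6 of 6, only restates the observation (5.51, 5.57 and 5.46 in control replicates 1 to 3, and 4.63, 4.63 and 4.94 in activated replicates 1 to 3). No value here tells exchanged labels from other differences between the 2 groups of cultures. A decrease of these transcripts in depolarised and then recovering cells, which may be biological, is only an example of these.

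Markers of the 4 non-neuronal groups were higher and neuron markers lower in the libraries labelled activated. With all libraries a lower share of neurons fits the non-neuronal side, where the 4 medians ranged over 0.18 (48 genes, permutation p = 0.661). Without activated replicate 1 they ranged over 0.48, from 0.31 to 0.80 (permutation p = 0.00254). Without any other single library the range lay between 0.12 and 0.31 (permutation p between 0.165 and 0.784). The permutations treat genes as independent, while estimated correlations were 0.52 among astrocyte and 0.79 among microglia markers. They therefore cannot decide whether the rise was common. A lower neuron share that moved all neuronal genes alike would leave unexplained the receptor and channel genes. Their median of 0.05 (54 genes) lay 0.37 above the −0.32 of the 34 neuron markers (permutation p = 1e-05, the smallest that the permutations allow). Their transcripts were longer, with list medians of 5431 (receptors) and 8386 bases (channels) against 4057 (excitatory) and 2664.5 (inhibitory markers). The gap was not retested with the length and GC offsets. A changed cell mixture may thus contribute, but it was left open for the glial part. For the neuronal part it was left open too, since the comparison assumes that neuronal genes move alike. Its permutations also treat genes as independent, while estimated correlations were 0.26 among receptor and 0.22 among channel genes. With a correction for transcript length it was not tested.

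TEC loci were higher for 361 and lower for 14 of 1509 tested (253 and 17 with total counts only, 961 and 1 under the neuron marker scaling). Loci inside a protein-coding gene on the same strand rose more than the others (medians 0.42 of 1209 and 0.33 of 300; difference 0.09, permutation p = 0.00014), which is consistent with more unspliced RNA as part of the cause. In activated replicate 3, with no excess of reads outside exons, the median deviation was −0.07 against −0.06 in the highest control library. This fits the share of reads outside exons alone. Those reads were not split into introns, stretches between genes and the opposite strand, so unspliced RNA itself was not measured. Whether any excess of unspliced RNA came from the cells or from RNA extraction and library preparation was not tested.

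Of the 10 ways to split the 6 libraries into groups of 3, the split by label called 2945 higher and 3733 lower genes and the highest other split called 0 in each direction, so 1 of 10 reached the real counts, and the share cannot go under 0.1.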

How the results depend on the processing

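Over the alternatives that keep all libraries, other than neuron marker scaling, 2089 to 3341 genes were higher and 3105 to 4576 lower, and with single libraries left out 1975 to 3304 and 2846 to 3908. Leaving out single libraries gave −0.38 to −0.55 for Rnmt, −0.67 to −0.85 for the rapid list and −0.17 to −0.23 for the cap list, with each call kept. Under the neuron marker scaling, chosen after seeing the data as were the length and GC offsets, 8814 genes were higher and 629 lower, because the scaling raises every log2 fold change by the fall of its markers. There Rnmt was at −0.16 with no call. Medians of called lists that reversed under it were 0.10 (cap), 0.0402 (circadian), 0.0125 (excitatory), 0.0061 (heat shock) and 0.19 (vesicle), and called genes that reversed were Eif4e2 (0.0691), Kcnc2 (0.0657), Ncbp1 (0.092), Ncbp2 (0.0177), Rpl3 (0.0527), Rpl7 (0.0561), Rpl8 (0.0543) and Rps4x (0.0371). These 5 lists passed there as lower than the other genes, whose median was raised to 0.35. Their camera adjusted p values were 0.0282 (cap), 0.022 (circadian), 0.011 (excitatory), 0.00569 (heat shock) and 0.00287 (vesicle). The scaling moves all genes alike, so it leaves the gap between a list and the other genes almost as it was. Passing there is therefore no separate support for these lists. With an estimated correlation the rapid list (−0.74) and the cap list (−0.21) were not called. The replicate block gave 2173 higher and 3105 lower genes, −0.47 for Rnmt, and medians of −0.75 and −0.22 for the rapid and cap lists, and the heat shock list was not called in it (−0.29, camera adjusted p = 0.0541). Same-numbered libraries did not deviate together (correlations −0.01, −0.18 and −0.21) and no library correlated best with its own number, so the numbers gave no sign of pairing. Length and GC offsets gave 3167 higher and 3579 lower genes. Of all 6678 changed genes, 99.9% kept their call with the likelihood-ratio test and 78.8% with the replicate block. Without control replicate 2 the share was 72.1%, and under the neuron marker scaling 53.5%. Single genes were followed for only 151 genes, picked by the rule for named genes or after their values were seen, so their stability does not stand for all genes. Of their 2412 gene and setting pairs, 2291 kept their call or lack of one, 96 lost a call, 17 gained one and 8 called values reversed. Of list and setting pairs, 335 kept their call or lack of one, 29 lost a call, 9 gained one and 5 called medians reversed, while medians with no call could turn sign without being counted as reversed. The cause of the other changes was not tested. What depth limits was not tested by thinning reads.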

Other observations

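Further groups of genes stood out when the data were read, and 13 families were tested, all chosen after their values had been seen. Cytoskeletal genes of neurons were lower in the libraries labelled activated: all 4 neurofilament genes fell (median −0.77; camera adjusted p = 0.000229, 0.152 with an estimated correlation), Nefh from 68.1 to 33.5 CPM, and 12 of 14 tubulin genes fell and 1 rose (median −0.48; camera adjusted p = 3.14e-06, 0.205 with an estimated correlation), Tubb3 from 463 to 268 CPM. Nuclear-encoded respiratory chain genes were lower too, with 53 of 76 lower and 2 higher (median −0.32, camera adjusted p = 6.31e-12, 0.152 with an estimated correlation, Atp5a1 −0.60, Cox5a −0.56). Mitochondrially encoded mRNAs went the other way, with 9 of 11 higher and none lower. Of 38 proteasome genes 34 fell (median −0.43; camera adjusted p = 6.31e-12, 0.218 with an estimated correlation; Psmb7 −0.54), and all 7 chaperonin genes fell (median −0.41; camera adjusted p = 8.71e-05, 0.219 with an estimated correlation; Cct6a −0.61). Of 47 replication-dependent histone genes 22 fell and 1 rose (median −0.48; camera adjusted p = 4.72e-07, 0.134 with an estimated correlation), among them Hist1h3e (−0.91), although copies of these genes share reads and single values are uncertain. Of 11 Bex and Tceal genes 9 fell (median −0.49; camera adjusted p = 2.24e-05, 0.152 with an estimated correlation; Bex2 −0.77). These decreases shrank under the neuron marker scaling. Respiratory chain genes were then 10 higher and 8 lower (median −0.02), proteasome genes 1 higher and 7 lower (−0.13), chaperonin genes 2 lower (−0.11) and tubulin genes 1 higher and 6 lower (−0.18). Histone genes were 3 higher and 10 lower (−0.17), Bex and Tceal genes 3 lower (−0.18), and all 4 neurofilament genes stayed lower (−0.46).

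Matrix and adhesion genes were higher in the libraries labelled activated, as were endothelial, mural and fibroblast markers (median 0.47) and astrocyte markers (0.59), with 21 of 40 collagen genes higher and none lower (median 0.44; camera adjusted p = 1.80e-06, 0.0536 with an estimated correlation; Col12a1 0.90, Col8a1 0.86). Of 22 integrin genes 12 rose and 1 fell (median 0.54; camera adjusted p = 0.000156, 0.219 with an estimated correlation; Itga1 0.81, Itgb1 0.54). Of 21 gamma protocadherin genes 6 rose and none fell (median 0.22; camera adjusted p = 0.000954, 0.219 with an estimated correlation; Pcdhgc3 0.50). With total counts only 3 gamma protocadherin genes were higher, with unstranded counts 2 of 20, and under the neuron marker scaling all 21, while collagen genes higher numbered 18, 20 and 31 and integrin genes 12, 12 and 19 in the same order. The 3 noncoding RNAs Meg3, Rian and Mirg of the imprinted locus on chromosome 12 rose (median 0.45; camera adjusted p = 0.045, 0.311 with an estimated correlation), but Meg3 lost its call without control replicate 2 (0.35) or activated replicate 2 (0.29), and Rian without control replicate 2 (0.23) or activated replicate 1 (0.22) and with total counts only (0.18). Of 13 small nucleolar RNA host genes 3 rose and none fell (median 0.22; camera adjusted p = 0.362), and of 331 zinc finger protein genes 30 rose and 51 fell, with a median of −0.00 that turned to 0.30 under the neuron marker scaling (camera adjusted p = 0.546). Medians of inhibitory and excitatory marker genes differed by −0.12 (permutation p = 0.505).

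Transcripts of the sex chromosomes differed most in activated replicate 1. Xist stood at 469, 378 and 450 CPM in control replicates 1, 2 and 3 and at 1173, 608 and 564 CPM in activated replicates 1, 2 and 3. In the same order, the Y-linked gene Ddx3y stood at 31.4, 34.4, 36.1, 11.4, 24.2 and 28.3 CPM, Uty at 20.3, 20.5, 22.6, 11.9, 28.0 and 23.9 CPM, Kdm5d at 23.3, 23.3, 23.3, 12.6, 31.4 and 26.7 CPM, and Eif2s3y at 28.1, 28.5, 28.8, 12.1, 34.3 and 28.0 CPM. The log2 fold change of Xist was 0.85, and 0.44 without activated replicate 1. Xist was higher and Ddx3y lower in all 3 libraries labelled activated (edgeR adjusted p = 0.00497 and 0.0228). The groups overlapped for Uty, Kdm5d and Eif2s3y, which were not called.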
